A study of Homo sapiens with 10 samples.

How the data were processed

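The data were 10 one-colour Affymetrix U133A arrays, each hybridised with total RNA of 1 primary ovarian carcinoma, 5 from patients with low and 5 from patients with high depression, per the labels. RNA was extracted from homogenised tissue with a column kit, per the labels' protocols. The deposited table holds log2 values per probe set, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, normalizes probe intensities to a common distribution and summarises each probe set by median polish, so small differences at low levels are compressed. Its version, the scan dates, the array batches and detection calls were not given in the sources used here, so no batch could be tested. Array medians of 4.99 to 5.11 lay close together in the deposited table, and no further normalization was applied for the main results.

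Probe sets were named through the platform annotation supplied with the table. Of the 22215 tested probe sets, 19065 were listed with 1 gene, 1043 with several and 2107 with none, and only those with 1 gene were named, covering 11963 genes. The gene identifiers led to 0 updated symbols in the gene table of assembly GRCh38.p14, which was used for names and chromosomes only. Names were checked against the values. Over 1976 pairs of probe sets of one gene, with an SD above 0.5, the median correlation across arrays was 0.916, against 0.190 and 0.164 when names were moved by 1 row up or down. It was 0.889 to 0.942 in 12 blocks of 2000 rows. Among the 68 control probe sets, 3 followed a control other than the one they name, so apart from the spike-in transcripts only the ACTB and GAPDH controls were used. Their 3' probe sets correlated at r 0.949 to 0.954 and 0.852 to 0.921 with the ordinary probe sets of the same genes.

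The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, two-sided), with Benjamini-Hochberg adjustment over the 22215 probe sets and a threshold of 0.05. Log2 differences are high minus low depression throughout, and folds are those of the difference of mean log2 values. Probe sets at least 1.5-fold apart were counted without a test. Gene lists were tested with camera on 1 probe set per gene, the one with the highest mean, with the preset correlation of 0.01. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of the list mean per tumour over all 252 assignments. Count and direction of list members are those of group means. The 34 lists, 18 of pathways and 16 of cell types, were fixed before the data were examined, as were the tests and the alternatives not named below as added. Of their 543 entries 482 were measured, and 11 pairs of lists share genes.

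Genes were named by a rule fixed at the same time. It takes up to 12 genes per direction with the largest difference among those past the adjusted threshold, with free places filled by genes with an unadjusted p under 0.01 and no overlap between the groups, reported as not past the threshold. It also takes the 2 to 4 members of smallest p in each list described with examples, and IL6, CXCL8, VEGFA, MMP2, MMP9, FOS and NR3C1 whatever their values. A further gene of this part of the rule is not reported here. Which lists were described with examples, and with how many, was chosen after the values were seen. Since no probe set passed, all 24 places were filled by the looser criterion. Genes whose level can tell a person's sex are not reported per tumour.

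The fit and the list tests were tested on simulated data with 5 arrays per group and the spread of the real probe sets, for the comparison of high with low depression. Among 22215 probe sets, 52.2% of the 67 changed by 1 log2 unit, 83.6% of the 67 changed by 2 and 90.9% of the 66 changed by 3 were recovered, with 9 false calls. A shift of 0.6 in the immediate early list was recovered at a camera adjusted p of 5.99e-11, with 0 of 31 lists without shared genes called. The simulated genes were independent, whereas the estimated correlation was 0.297 in the real immediate early list and 0.682 in the fibroblast list. The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists in the real tumours.

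The alternatives chosen beforehand were equal array medians, quantile normalization, a filter on low probe sets, each tumour left out in turn, the replicate number as a block, 1 probe set per gene or the mean of a gene's probe sets, trend and robust eBayes, array weights, values below 4 set to 4, other thresholds and list tests, and the ACTB 3' to 5' signal or a stroma minus epithelial marker mean as a covariate. Leaving out the 2 low depression tumours with the highest ACTB 3' to 5' signal, and the spike-in level as a covariate, were added after the data were seen. The tumours of the groups share replicate numbers, which were not used to pair them in the main fit. Correlations across the 10 tumours used 100000 permutations. With 5 tumours per group, the smallest two-sided exact p is 0.00794.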

Results

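Gene expression was measured in 10 primary ovarian carcinomas, each from a different patient, with 1 Affymetrix U133A array per tumour. This one-colour array reads a transcript with sets of short probes, so that a gene can have several probe sets. The tumours formed 2 groups of 5, from patients with low and with high depression, and the question of the series was whether tumour expression differed between them. The deposited log2 values covered 22215 tested probe sets and 68 controls. Array medians lay between 4.99 and 5.11, and arrays correlated with each other at r 0.882 to 0.964 across probe sets, which are not independent replicates. The median SD between tumours of one group was 0.313 on the log2 scale, and the number of arrays limits the precision of each difference below.

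The largest differences among genes that separated the groups were those of PLAT and CCN2, both higher in tumours of patients with high depression. PLAT, the tissue plasminogen activator, averaged 7.90 ± 0.38 (SD, n = 5) in the high depression group and 5.59 ± 1.24 (n = 5) in the low depression group, a 4.97-fold difference. CCN2, a secreted connective tissue growth factor, averaged 8.44 ± 0.87 against 6.26 ± 0.53, a 4.52-fold difference. CPE, a carboxypeptidase of prohormone processing, was 3.02-fold higher, and WASHC3, a subunit of the endosomal WASH complex, was 2.99-fold higher, at 7.08 ± 0.22 against 5.50 ± 0.50. The lysosomal protease CTSB was 2.12-fold higher, and CST3, or cystatin C, an inhibitor of cysteine proteases, was 2.04-fold higher.

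The other genes that the naming rule placed on the higher side were SERPING1, the complement C1 inhibitor, with a log2 difference of 1.40, DIPK1A with 1.28, ANKRD6 with 1.17, the semaphorin receptor PLXNC1 with 1.07, PLA2G7, which degrades platelet-activating factor, with 1.04, and the tetraspanin TSPAN4 with 0.99. On the lower side, the quinone reductase NQO2 had the largest difference, -1.08 ± 0.34 (SE), with means of 6.05 ± 0.23 (SD) against 7.12 ± 0.79. SURF2 averaged 5.36 ± 0.26 against 6.17 ± 0.19, a difference of -0.81 ± 0.15 (SE). The remaining genes on that side were BSPRY (-0.96), the multivitamin transporter SLC5A6 (-0.90), SNAPC4 of the complex that activates small nuclear RNA genes (-0.78), the arginine methyltransferase CARM1 (-0.75), the zinc finger genes ZNF432 (-0.73) and ZNF419 (-0.55), DMAC2, an assembly factor of the mitochondrial respiratory chain (-0.72), PTOV1 (-0.70), the F-box gene FBXO42 (-0.62) and DRC4 of the dynein regulatory complex (-0.58). The naming rule required that the probe set named for each of these 24 genes have all 5 values of one group beyond all 5 of the other. This separation is therefore not a result, and none passed the adjusted threshold. The brightest probe set of CTSB overlapped between the groups, at a 1.58-fold difference.

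**Figure D1:**
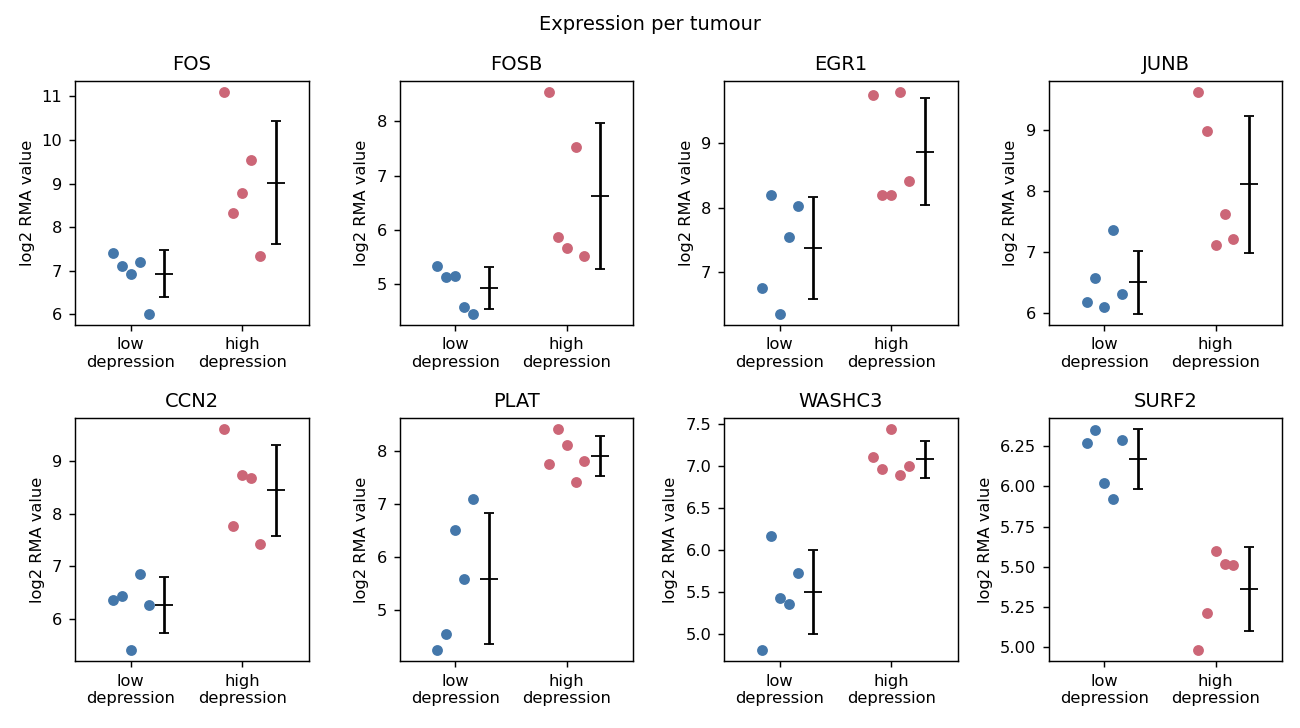
Expression of 8 genes in each tumour, as log2 RMA values on the vertical axes, for the low and high depression groups of 5 tumours. Points are tumours, and the horizontal mark with its bar is the group mean ± SD. The values of FOSB, CCN2, PLAT and WASHC3 in the high depression group all lie above those of the low depression group, those of SURF2 all lie below, and FOS, EGR1 and JUNB overlap between the groups.

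Across the 22215 probe sets, limma's moderated test called 0 at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.685, for WASHC3 among others. At an unadjusted p under 0.05 there were 914 probe sets, 437 higher and 477 lower, where chance gives 1111. The exact rank comparison left 156 probe sets without overlap between the groups, 58 higher and 98 lower, where chance gives 176, or 0.794% of them. Group means differed by at least 1.5-fold in 1389 probe sets, 1018 higher and 371 lower, and by at least 2-fold in 257, 218 higher and 39 lower. Over all 22215 probe sets, 42.8% were higher, with a median log2 difference of -0.034. Of the 1389, 73.3% were higher, against 60.7% of 1867 with the ratio of linear means and 66% of 1360 after quantile normalization. The share was 53.2% (972 higher, 854 lower) without low depression tumours 1 and 4, whose arrays had the highest 3' to 5' signal of ACTB.

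That signal, a sign of RNA quality in which higher values mean a weaker signal from the 5' end of the transcript, was 2.25 and 2.77 log2 units in low depression tumours 1 and 4, and between 0.58 and 1.65 in the other 8. The group means were 1.15 ± 0.457 (SD) for high and 1.61 ± 0.842 for low depression, a difference of -0.462 (exact two-sided permutation p = 0.341). For GAPDH they were 0.616 ± 0.167 and 0.970 ± 0.664, a difference of -0.354 (exact permutation p = 0.365). The same 2 tumours had the highest spike-in signal, 9.67 and 9.20 against 7.95 to 8.42 in the others.

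Immediate early genes, the transcription factors and feedback regulators induced within minutes by many stimuli, were higher in the high depression group as a set. All 16 measured members had a higher mean there, by 1.13 log2 units on average (median 1.06), and the list mean was 8.23 ± 0.705 (SD, n = 5) against 7.11 ± 0.256 (n = 5), with no overlap between tumours. FOS averaged 9.02 ± 1.41 against 6.92 ± 0.54, a 4.27-fold difference. JUNB was 3.04-fold higher, EGR1 2.81-fold, and ZFP36, which promotes decay of inflammatory transcripts, 2.13-fold. None of the 16 passed the threshold over all probe sets, and 7 passed adjusted over the list alone, FOS, JUNB, EGR1 and ZFP36 each at 0.0334. By camera with the preset correlation, the list passed at an adjusted p of 6.64e-13, and the call was lost at adjusted p = 0.134 with an estimated correlation. The exact permutation p of the list mean was 0.00794, the smallest that 5 against 5 allows, or 0.0899 adjusted over 34 lists.

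Targets of cAMP and CREB, the signalling route downstream of beta-adrenergic receptors, had 13 of 17 measured members higher and 4 lower, with a mean difference of 0.536. The tumours of the groups did not overlap in the list mean, 5.99 ± 0.182 (SD, n = 5) against 5.46 ± 0.217 (n = 5). FOSB was 3.23-fold higher, the phosphatase gene DUSP1 2.38-fold, and RGS2, a regulator of G protein signalling, 1.67-fold. The nuclear receptor NR4A3 had a log2 difference of 0.83 on its brightest probe set, or 0.45 without high depression tumour 3, but both of its other probe sets went the other way. Camera gave an adjusted p of 0.00125, against an adjusted p of 0.166 with an estimated correlation, and 0 members passed adjusted over the list alone. The list shares 2 genes with the immediate early list, FOSB and DUSP1. These were also its only members at an unadjusted limma p under 0.05, so the 2 lists are not separate evidence. Without them its difference was 0.411 (exact permutation p = 0.0317, against 0.00794 with them).

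Genes of the STAT3 and IL-6 pathway had 12 of 15 members higher and 3 lower, by a smaller mean difference of 0.251, with list means of 6.78 ± 0.104 (SD, n = 5) and 6.52 ± 0.102 (n = 5) that did not overlap. SOCS3, the feedback inhibitor of this pathway, was 1.63-fold higher, and the kinase gene PIM1 was 1.28-fold higher. Both passed adjusted over the list alone, at 0.0461, and neither over all probe sets. CEBPB, a transcription factor of the acute phase response, was 1.48-fold higher, and all 5 values lay above those of the low depression group. Its log2 difference was 0.56, or 0.37 without low depression tumour 1. IL6 itself averaged 4.88 ± 0.36 against 4.46 ± 0.35, a difference of 0.43 ± 0.21 (SE). Camera gave an adjusted p of 0.00138 and lost the call at adjusted p = 0.134 with an estimated correlation. That correlation was -0.0296, below the preset 0.01, so the loss did not come from correlation between members. By fry, which tests whether the members move one way on balance, the adjusted p was 0.0306. The STAT3 list was the 1 list of 34 that fry called, and its exact permutation p was 0.00794 (0.0899 adjusted).

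**Figure D2:**
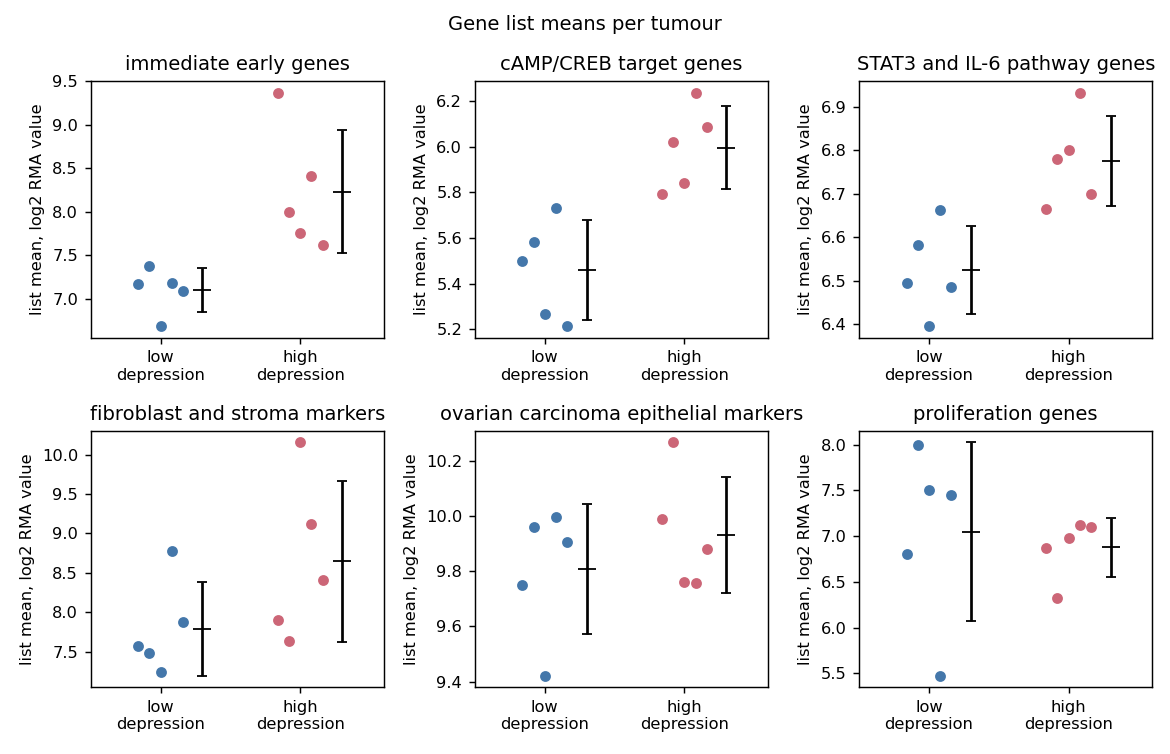
Mean log2 RMA value over the measured genes of 6 lists in each tumour, for the low and high depression groups of 5 tumours. Points are tumours, and the horizontal mark with its bar is the group mean ± SD. The immediate early, cAMP/CREB and STAT3 lists separate the groups, while the fibroblast, epithelial and proliferation lists overlap.

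The parts of the adrenergic pathway themselves were balanced, with 10 of 20 members higher and 10 lower and a mean difference of 0.0449 (camera adjusted p = 0.846). PRKAR1A, a regulatory subunit of protein kinase A, had a log2 difference of 0.59. The beta-adrenergic receptor ADRB3 had one of -0.28, at low levels of 4.33 in the high and 4.61 in the low depression group. The median over probe sets was 5.08. Genes of monoamine and catecholamine metabolism had 6 members higher and 10 lower (mean -0.0102, camera adjusted p = 0.798). Their list means were also low, at 4.45 and 4.46, which limits what a lack of difference shows. NR3C1, the glucocorticoid receptor, differed by 0.04 ± 0.32 (SE), or by -0.20 without low depression tumour 3 and 0.22 without low depression tumour 2. Glucocorticoid response genes had 13 of 14 members higher and 1 lower, by 0.351 on average, and 0 passed adjusted over the list alone. Among the higher ones were DUSP1, which is also on the immediate early and cAMP/CREB lists, the kinase gene SGK1 (1.69-fold) and the protease inhibitor SERPINA3 (1.83-fold). The log2 difference of SERPINA3 was 0.53 without high depression tumour 3. Their camera adjusted p was 0.0105, and the call was lost at adjusted p = 0.508 with an estimated correlation. It was also lost without low depression tumour 3 (0.166), at a difference of 0.217.

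NF-kB target inflammatory genes had 16 of 19 members higher and 3 lower, by 0.248 on average. The chemokine gene CCL2 was 2.26-fold higher and NFKB1 1.73-fold, whereas TNF had a log2 difference of -0.76, or -0.48 without low depression tumour 2. That of CCL2 was 1.17, or 0.76 without low depression tumour 3. CXCL8, which encodes interleukin 8, had one of 0.83 ± 0.70 (SE), or 0.39 without low depression tumour 3. None passed adjusted over the list alone (0 of 19). The camera adjusted p was 0.0496, against an adjusted p of 0.828 with an estimated correlation. The call was lost without low depression tumour 3 (0.959, with a list difference of 0.0212) and without high depression tumours 4 (0.377, with 0.155) and 5 (0.167).

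Fibroblast and stroma markers had all 17 measured members higher, by 0.855 on average (median 0.778), although the list means of 8.64 ± 1.02 (SD, n = 5) and 7.79 ± 0.596 (n = 5) overlapped between tumours. The small leucine-rich proteoglycans LUM and DCN were 3.21-fold and 1.92-fold higher. COL11A1, a fibrillar collagen gene, averaged 7.91 ± 2.02 against 5.75 ± 1.54, and COL1A1 was 1.77-fold higher on its brightest probe set, with 1 of its 3 others going the other way. The log2 difference of COL1A1 was 0.53 without high depression tumour 3. Of these genes, 0 passed adjusted over the list alone. Camera gave an adjusted p of 2.08e-07, which was lost at adjusted p = 0.508 with an estimated correlation, and the exact permutation p of the list mean was 0.127. High depression tumour 3, with a list mean of 10.2, carried much of the difference, which was 0.477 without it (camera adjusted p = 0.000641).

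Mesenchymal transition genes had 14 of 15 members higher and 1 lower, by 0.542 on average, with log2 differences of 1.04 for SPARC, 0.59 for S100A4 and 0.68 for TGFB1, whose single other probe set went the other way. That of TGFB1 was 0.44 without high depression tumour 5. None passed adjusted over the list alone (0 of 15). Camera gave an adjusted p of 1.07e-05, against an adjusted p of 0.282 with an estimated correlation, and the exact permutation p was 0.0476 (0.324 adjusted). Matrix proteases and their inhibitors had 15 of 19 members higher and 4 lower, by 0.413 on average. PLAT was the 1 member that passed adjusted over the list alone, at 0.0260. TIMP1, an inhibitor of metalloproteinases, was 1.82-fold higher, with a log2 difference of 0.87, or 0.55 without low depression tumour 3, and CTSB was 1.58-fold higher on its brightest probe set. MMP2 differed by 0.49 ± 0.53 (SE), or by 0.16 to 0.86 without single tumours, and MMP9 by 0.32 ± 0.95, or by -0.42 to 0.76. The lowest of these values came without high depression tumour 3 for MMP2 and tumour 5 for MMP9, and the highest without high depression tumour 2 and low depression tumour 5. The camera adjusted p of the list was 0.00233, lost at adjusted p = 0.508 with an estimated correlation and without high depression tumour 5 (0.0876). With the mean of the fibroblast minus the epithelial markers as a covariate, neither the mesenchymal (0.296, adjusted p = 0.0572) nor the protease list (0.140, adjusted p = 0.458) passed.

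Endothelial markers had 10 of 13 members higher and 3 lower, by 0.186 on average. VWF, a product of endothelial cells, was 1.24-fold higher (a log2 difference of 0.31, or 0.17 without low depression tumour 4), the receptor gene TIE1 1.21-fold, and ERG 1.22-fold on its brightest probe set, while both other ERG probe sets went the other way. None passed adjusted over the list alone (0 of 13). Camera gave an adjusted p of 0.0139, lost at adjusted p = 0.282 with an estimated correlation, and the exact permutation p was 0.0476. The call was also lost without low depression tumours 2 (0.0534) and 3 (0.161) and without high depression tumour 5 (0.0750). Angiogenic factors and receptors had 10 members higher and 9 lower (mean 0.104, camera adjusted p = 0.725), and passed at 0.245 without low depression tumours 1 and 4 (adjusted p = 0.0181, against 0.380 with an estimated correlation). Among them ANGPT2 had a log2 difference of -0.13, or -0.08 without low depression tumour 2. VEGFA had one of -0.16 ± 0.22 (SE), or of -0.35 to -0.05 without single tumours, with 2 of its 3 other probe sets going the other way.

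Antigen presentation and several immune cell lists had mostly higher members, with wide spread between tumours. Of the MHC class II genes, 10 of 12 were higher and 2 lower, by 0.714 on average, with HLA-DMB 1.74-fold higher. The class II transactivator CIITA had a log2 difference of -0.20 and HLA-DOA one of -0.34, or -0.23 without low depression tumour 4, with 1 of 3 other HLA-DOA probe sets going the other way. Of the MHC class I genes, 10 of 11 were higher and 1 lower, by 0.398 on average, with HLA-B 2.05-fold and HLA-C 1.69-fold higher. Macrophage markers had 12 of 13 members higher and 1 lower, by 0.426 on average, with the scavenger receptor CD163 1.95-fold and the mannose receptor MRC1 1.45-fold higher. B and plasma cell markers had 10 of 14 members higher and 4 lower, by 0.462 on average. The immunoglobulin light chain gene IGKC was 2.97-fold higher (9.42 ± 2.69 against 7.85 ± 0.68), with 2 of its 7 other probe sets going the other way. Its values in high depression tumours 1 (6.62) and 2 (6.57) lay below every value of the low depression group, and its log2 difference of 1.57 was 0.79 without high depression tumour 5. CD22 was 1.22-fold higher, and CD163 had a log2 difference of 0.97, or 0.53 without high depression tumour 5. That of HLA-C was 0.76, or 0.37 without low depression tumour 3. In each of these 4 lists, 0 members passed adjusted over the list alone.

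The camera adjusted p was 0.0349 for MHC class II, 0.0381 for macrophage, 0.0426 for MHC class I and 0.0496 for B and plasma cell genes, and for each the call was lost at adjusted p = 0.828 with an estimated correlation. The MHC class II call was lost without low depression tumour 3 (0.551) and without high depression tumours 2 (0.0547), 4 (0.203) and 5 (0.266). That of macrophages was lost without low depression tumours 2 (0.0591, at a difference of 0.453) and 3 (0.551) and high depression tumours 3 (0.0523), 4 (0.316) and 5 (0.686). For MHC class I the tumours were low depression 3 (0.855), 4 (0.107) and 5 (0.201) and high depression 4 (0.245) and 5 (0.456). For B and plasma cell markers they were low depression 2 (0.255), 3 (0.244) and 5 (0.0780) and high depression 4 (0.0688) and 5 (0.991). The mean difference of the B and plasma cell list was 0.0237 without high depression tumour 5, and those of the MHC class I, MHC class II and macrophage lists were 0.0537, 0.380 and 0.197 without low depression tumour 3. Without high depression tumour 1 the differences were larger, at 0.677 for MHC class I, 1.13 for MHC class II, 0.807 for macrophages and 0.719 for B and plasma cells, and without low depression tumour 2 that of MHC class I was 0.732. Those of the macrophage list were 0.240 and 0.130 without high depression tumours 4 and 5, and that of MHC class I was 0.146 without the latter.

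Interferon response genes had 17 of 19 members higher and 2 lower, by 0.346 on average (camera adjusted p = 0.125), with the chemokine genes CXCL11 at 4.54 ± 1.94 (SD) against 3.41 ± 0.25 and CXCL9 at 6.06 ± 2.25 against 4.94 ± 0.27. Both rested on few tumours, since without high depression tumour 5 the log2 difference of CXCL9 was 0.27 in place of 1.12 and that of CXCL11 0.41 in place of 1.14. CXCL9 in high depression tumours 1 (4.03) and 2 (4.18) lay below every value of the low depression group, and the list difference was -0.130 without tumour 5. T cell markers had 9 of 16 members higher (mean 0.225, camera adjusted p = 0.440), and cytotoxic and NK cell markers 10 of 14 (mean 0.279, camera adjusted p = 0.224). Neutrophil markers had 5 members higher and 7 lower (mean -0.0207, camera adjusted p = 0.818), and mast cell markers 3 and 3 (mean -0.0333, camera adjusted p = 0.863). List means in the high and low depression groups were low, at 4.59 and 4.31 for cytotoxic and 4.65 and 4.67 for neutrophil markers. This limits what a lack of difference shows. Interferon genes passed without low depression tumours 1 (0.0156) or 2 (0.00275) or high depression tumours 1 (0.00424), 2 (0.00738) or 3 (0.0229). T cell markers passed without high depression tumour 1 (0.0297), and cytotoxic markers without high depression tumours 1 (0.0297) or 3 (0.0496). All these calls used camera's preset correlation of 0.01. The estimated correlations with all tumours were 0.78 for interferon, 0.585 for T cell and 0.648 for cytotoxic genes. With them, camera gave each of these lists an adjusted p of 0.936.

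Heat shock and unfolded protein genes had 12 of 14 members higher and 2 lower, by 0.193 on average. HERPUD1, induced by stress of the endoplasmic reticulum, was 1.67-fold higher and the chaperone gene HSP90AB1 1.46-fold, with a log2 difference of 0.54, or 0.28 without low depression tumour 1. None passed adjusted over the list alone (0 of 14). The camera adjusted p was 0.0381, lost at adjusted p = 0.582 with an estimated correlation. The call was also lost without low depression tumours 1 (0.0831), 4 (0.197) and 5 (0.156) and without high depression tumours 4 (0.174) and 5 (0.168). The difference was 0.0931 without low depression tumour 4 and 0.304 without low depression tumour 2. Without low depression tumours 1 and 4 together, both with high 3' to 5' signal, the difference of this list was -0.0109 and that of HSP90AB1 -0.0347.

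Carcinoma cell and metabolic lists did not pass with all tumours. Ovarian carcinoma epithelial markers had 13 of 20 members higher and 7 lower (mean 0.124, or 0.0272 without low depression tumour 3, camera adjusted p = 0.422). Among them WT1, a nuclear marker of serous carcinoma, was 1.42-fold higher and the protease inhibitor SLPI 1.92-fold, whereas CDH1, the epithelial cadherin, had a log2 difference of -0.58. Hypoxia response genes had 4 members higher and 12 lower (mean -0.201, camera adjusted p = 0.0938). NDRG1 was at -1.02, or -0.68 without low depression tumour 1. ERO1A, an oxidase of the endoplasmic reticulum, was at -0.46, or -0.29 without low depression tumour 2. Proliferation genes had 8 higher and 14 lower (mean -0.171, camera adjusted p = 0.595). The proliferation antigen gene MKI67 had a log2 difference of -0.96, and the mitotic kinase gene BUB1 one of -0.61, with 1 of its 4 other probe sets going the other way. Without low depression tumours 1 and 4, the hypoxia list was at -0.257 (adjusted p = 0.0181, against 0.502 with an estimated correlation) and the proliferation list at -0.776 (adjusted p = 4.89e-14, against 0.110 with an estimated correlation). These 2 tumours have the lowest proliferation means of their group, 6.80 and 5.47, so leaving them out raises the mean of that group. The hypoxia list also passed without low depression tumour 4 (0.0243) or high depression tumours 1 (0.0418) or 3 (0.0201), and the proliferation list without low depression tumour 4 (1.95e-07). Low depression tumour 2 went the other way. Without it the hypoxia list was at -0.0652 (adjusted p = 0.617), the proliferation list at 0.0680 (adjusted p = 0.503), MKI67 at -0.50 and BUB1 at -0.20. Ribosomal protein genes had 6 higher and 9 lower (mean -0.0133, camera adjusted p = 0.946), and oxidative phosphorylation genes 7 and 10 (mean -0.0198, camera adjusted p = 0.980, with camera's direction, relative to the other genes, upward). The latter passed at -0.205 (adjusted p = 0.0171, against 0.546 with an estimated correlation) without low depression tumours 1 and 4, and without tumour 4 alone (0.0391).

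The remaining cell type lists did not pass camera with all tumours either. Smooth muscle and pericyte markers had 6 members higher and 4 lower (mean 0.231, adjusted p = 0.151), mesothelial markers 4 and 3 (mean 0.299, adjusted p = 0.637), and adipocyte markers 5 and 4 (mean 0.122, adjusted p = 0.595). Smooth muscle markers passed without low depression tumour 4 (0.00336) or high depression tumour 2 (0.0357), and without low depression tumours 1 and 4 together (0.0178, against 0.399 with an estimated correlation), but their difference was 0.0668 without high depression tumour 4. That of mesothelial markers was 0.0646 without low depression tumour 3. Ovarian stroma and steroidogenic markers had 4 higher and 7 lower (mean -0.0218, adjusted p = 0.798). Their list means were low, at 4.12 in the high and 4.15 in the low depression group. Those of adipocyte markers were 4.47 and 4.35. Such low levels limit what a lack of difference shows. For 3 lists the mean and median differed in sign. These were erythroid markers (mean 0.0810, median -0.106, adjusted p = 0.593 downward), platelet markers (mean 0.102, median -0.014, adjusted p = 0.798) and nerve and Schwann cell markers (mean 0.0847, median -0.016, adjusted p = 0.762). Without single tumours, their means ranged from 0.00267 to 0.241 for erythroid, 0.0551 to 0.178 for platelet and 0.0332 to 0.155 for nerve markers.

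**Figure D3:**
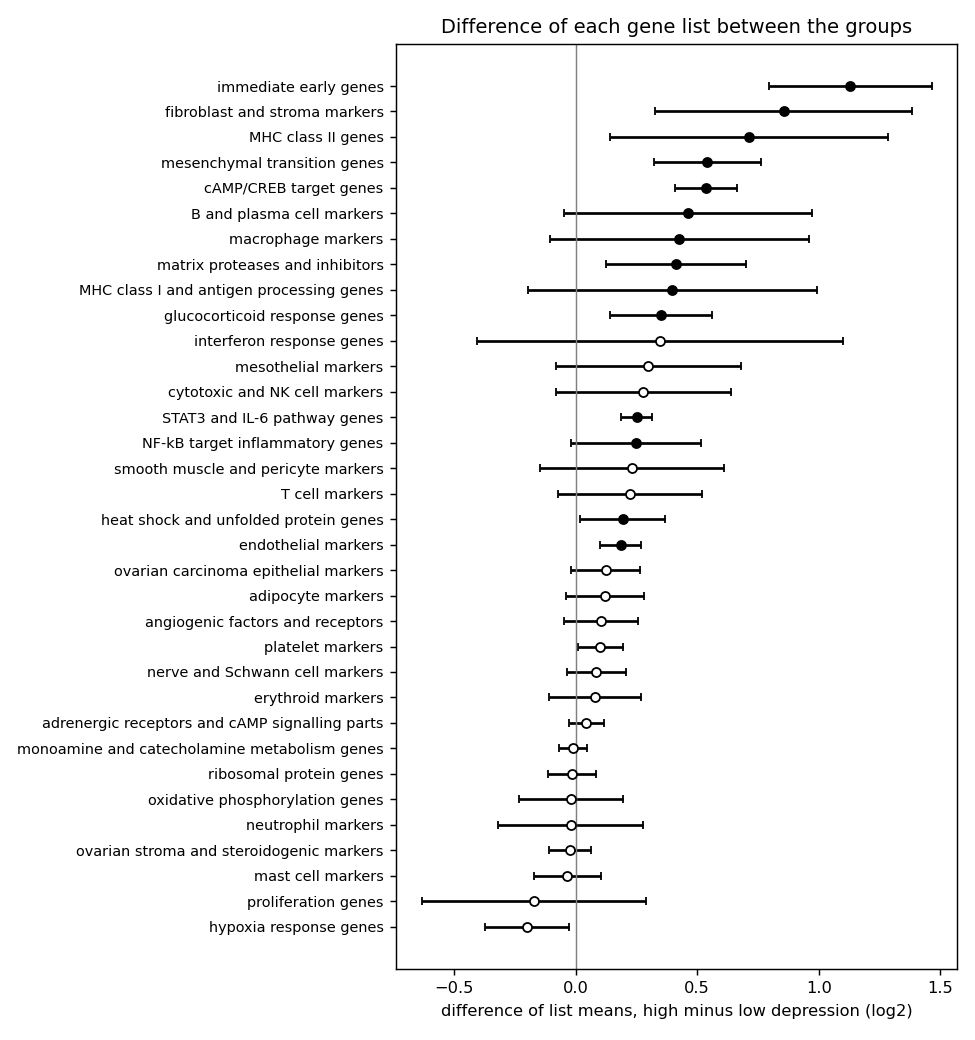
Difference of the mean log2 RMA value of each of the 34 gene lists, high minus low depression, on the horizontal axis, with bars of 1 SE from the 5 tumours per group. Filled points are the 14 lists that passed camera with the preset correlation, and open points did not pass. The immediate early list has the largest difference, 1.13.

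In all, camera with the preset correlation called 14 of the 34 lists, each of them higher in the high depression group, and 15 had an unadjusted p under 0.05. With an estimated correlation it called 0, fry called 1, and the exact permutation test called 0 after adjustment and 5 at an unadjusted p under 0.05. With so few lists at the smallest exact p of 0.00794, the exact test could not pass after adjustment over the 34 lists. Without a single tumour the count ranged from 6, without high depression tumour 5, to 18, without high depression tumour 1, and it was 7 without low depression tumour 3 and 8 without high depression tumour 4. With the fibroblast minus epithelial marker mean as a covariate camera called 2 lists, the immediate early and cAMP/CREB lists, and the STAT3 list had an adjusted p of 0.0572. With only probe sets above the median level it called 9.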

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

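The rule on gaps was set before the data were examined, but the genes it was applied to came in part from lists chosen for description after the values were seen. Among the 5 tumours of each group, a value stands out here when its gap to the nearest other tumour takes more than 0.71 of the group's range. Of 236 sets of 5 values examined, 6 stood out, where chance gives about 12, so they form no pattern beyond chance. The mean of the MHC class II genes in high depression tumour 1 was 6.11, against 7.92 in the nearest tumour of its group. The mean of the cytotoxic and NK cell markers in high depression tumour 5 was 5.99, with the next at 4.42. NQO2 had a log2 value of 5.66 in high depression tumour 1, with the nearest at 6.10. CEBPB had 9.06 in low depression tumour 1, with the nearest at 9.89. ERO1A had 5.96 in low depression tumour 2, with the next at 5.19. VWF had 8.12 in high depression tumour 1, with the next at 7.59.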

How the results depend on the processing

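The alternatives that left out low depression tumours 1 and 4 or used the spike-in level as a covariate were chosen after the results were seen. Limma called 0 probe sets under every normalization, filter, covariate and weighting tried, without each tumour (0 to 0) and at an adjusted p under 0.1. By construction, looser criteria gave more, 914 at an unadjusted p under 0.05, 142 under 0.01 and 156 without overlap. Probe sets at least 1.5-fold apart numbered 1243 to 1829 without single tumours, 1360 after quantile normalization and 1826 without the pair. They numbered 900 with 1 probe set per gene (fewer tested), and 257 were at least 2-fold apart. Without low depression tumour 4 alone, 1029 were higher and 625 lower at 1.5-fold, against 1018 and 371 with all tumours. Lists past camera, 14 higher and 0 lower with all tumours, numbered 6 to 18 without single tumours (13 higher and 3 lower without low depression tumour 4), 12 after quantile normalization (11 and 1), 14 with array weights (13 and 1), 18 with the ACTB covariate (16 and 2), 17 with the spike-in covariate (15 and 2), 18 without the pair (15 and 3), 9 with the filter (8 and 1, fewer genes), 2 with the stroma covariate (immediate early and cAMP/CREB, both higher), 0 with an estimated correlation, with all tumours or without the pair, 1 with fry and 0 with the exact test. The immediate early, cAMP/CREB, STAT3, mesenchymal and fibroblast calls held without each single tumour. ACTB 3' to 5' differences ranged from -0.625 to -0.173 and those of GAPDH from -0.487 to -0.109 without single tumours. Signs that turned belonged to values that had not passed, apart from the heat shock list, and the cause was not tested. After quantile normalization NR3C1 was at -0.0404, monoamine genes at 0.00247 and ovarian stroma at 0.0107. Monoamine genes were at 0.036 with the filter, and MMP9 at -0.12 with array weights. With the ACTB covariate, monoamine genes were at 0.0126 and mast cell markers at 0.0473. With the stroma covariate, NR3C1 was at -0.10, MMP2 at -0.16, ribosomal genes at 0.0397, oxidative phosphorylation at 0.0525, monoamine genes at 0.0139, smooth muscle at -0.127, mast cells at 0.00762, ovarian stroma at 0.0498 and adipocytes at -0.0326. Without the pair, VEGFA was at 0.00267, HSP90AB1 at -0.0347, heat shock genes at -0.0109, monoamine genes at 0.0112, mast cells at 0.0618, erythroid markers at -0.0384 and nerve markers at -0.0441. With the spike-in covariate, VEGFA was at 0.00356, monoamine genes at 0.00337, mast cells at 0.0357 and erythroid markers at -0.0118. Without single tumours, signs turned within the ranges -0.42 to 0.76 for MMP9, -0.20 to 0.22 for NR3C1, -0.00512 to 0.0870 for adrenergic parts, -0.130 to 0.700 for interferon, -0.00697 to 0.188 for angiogenic, -0.564 to 0.0680 for proliferation, -0.0794 to 0.0334 for ribosomal, -0.174 to 0.148 for oxidative phosphorylation and -0.0487 to 0.0229 for monoamine genes. For cell types they were -0.0409 to 0.366 for T, -0.0704 to 0.390 for cytotoxic, -0.195 to 0.181 for neutrophil, -0.115 to 0.0394 for mast, -0.0701 to 0.0472 for ovarian stroma and -0.0112 to 0.192 for adipocyte markers. Probe sets near background limit what can be seen, as the lower quartile of their means was 3.98 against a median of 5.08.

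Same-numbered tumours correlated in their deviations from the group means at r -0.168 to 0.085, and 0 of 5 correlated best with their own number. The main fit without pairs was set beforehand, since the labels name no pairing. Such correlations cannot tell whether patients of the same number were matched. With the replicate block, limma called 0 probe sets, 1389 were at least 1.5-fold apart, and camera called 13 lists, without MHC class I (adjusted p = 0.0828). The block left the ACTB 3' to 5' difference at -0.462 (exact sign-flip p = 0.375) and that of GAPDH at -0.354 (p = 0.438).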

Other observations

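Chosen after the results were seen were the tests without low depression tumours 1 and 4 or 4 alone, those on chromosomes, principal components and splits of the tumours (apart from counting the 1.5-fold probe sets over splits), and the use of list differences and the stroma covariate to weigh explanations, while the exact tests of list means over all tumours and the covariate itself were chosen beforehand. Proliferation genes depended on low depression tumour 4, whose list mean of 5.47 was the lowest of the 10. With it, their difference was -0.171 (exact permutation p = 0.738). Without it, the difference was -0.564 (exact permutation p = 0.0794), and without low depression tumours 1 and 4 it was -0.776, with means of 6.88 ± 0.326 (SD, n = 5) and 7.65 ± 0.303 (n = 3). That exact permutation p of 0.0179 is the smallest such groups allow, the adjusted p with an estimated correlation was 0.110, and the 2 tumours left out have the lowest means of their group.

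Of the 51 genes that lay lower in the high depression group without overlap, 11 lie on chromosome 19, or 21.6% against 6.77% of the 11963 genes (Fisher's exact test p = 0.000499, 0.0115 adjusted over 23 chromosomes). They included CARM1, PTOV1, ZNF432 and ZNF419. The mean difference over the 810 genes of that chromosome was -0.0856 (exact permutation p = 0.0873, 0.670 adjusted). Chance cannot be excluded for this grouping, since 49 of 100 splits of the tumours gave as small a p on some chromosome, the lowest 9.74e-30, and what sets those splits apart was not tested. The first principal component held 25.8% of the variance and did not separate the groups (exact permutation p = 0.651), nor did the second with 16.1% (p = 0.675), while the third, with 13.8%, differed between the groups at an exact permutation p of 0.0397, not adjusted for the 3 components. The first followed the ACTB 3' to 5' signal over the 10 tumours (r = 0.768, permutation p = 0.00817; rho = 0.782, p = 0.0106; r = 0.699 without the 2 tumours farthest from the median), but with adjusted p of 0.281 and 0.186 over 35 relations it passed no correction.

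Of the 126 distinct splits of the tumours into 5 and 5, 100 including the real one were drawn. For the number of probe sets past the adjusted threshold the splits decide nothing, since the real count of 0 is met by all 100 whatever their values (highest other 1). Chance cannot be excluded for the 1389 probe sets at least 1.5-fold apart (51 splits, highest other 2964) or for the 14 lists called by camera (12 splits, highest other 21). Lists whose means separated the groups numbered 3, and 3 of the 100 splits gave as many, the highest other being 6. The share of 1.5-fold probe sets that went one way was 73.3%, and 4 splits gave as large a share, the highest other being 77.9%. Taken alone, these 2 counts are under 5 in 100. They are uncorrected, however, were picked after the results were seen and stand among several such counts, so chance is not excluded for them. Each of the 3 lists had an exact permutation adjusted p of 0.0899, the lowest that 3 lists at the smallest exact p can reach over 34 lists. That adjusted p could not have passed, so it decides nothing about chance.

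The higher immediate early genes in tumours of patients with high depression are the first pattern to weigh. Low RNA quality in low depression tumours 1 and 4 is argued against by a list difference of 1.17 ± 0.374 (SE) without them, and a larger share of stroma by a difference of 1.26 ± 0.374 (SE) with the stroma minus epithelial mean as a covariate. Stress of the tissue between surgery and freezing, which can induce these genes, stays open, since the heat shock list differed by 0.193 ± 0.176 (SE; exact permutation p = 0.302) with all tumours and by -0.0109 without low depression tumours 1 and 4, and handling times were not used here. HSPA1A, HSPA1B and HSPA8 of that list were not measured, so it reads such stress only in part. The difference in depression itself stays open as untested, and the list of adrenergic receptors and cAMP signalling parts differed by 0.0449.

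The higher fibroblast and stroma markers are the second pattern, with an exact permutation p of 0.127 for the list mean. A lower share of carcinoma cells stays open, since the fibroblast list moved apart from the smooth muscle list by 0.623 (exact permutation p = 0.0397), but by 0.385 without high depression tumour 3 (p = 0.0556), and the p lay above 0.05 without 7 of the 10 tumours. The epithelial list was higher rather than lower, by 0.124 (exact permutation p = 0.429), or by 0.0272 without low depression tumour 3. The difference did not shrink without low depression tumours 1 and 4, whose arrays had the highest 3' to 5' signal of ACTB. Without them the difference was 1.11 ± 0.491 (SE; exact permutation p = 0.107). Low depression tumour 4 had the highest list mean of its group, 8.775, so leaving it out raised the difference. The fits with the ACTB 3' to 5' signal or the spike-in level as a covariate were not used here to weigh how RNA quality shifts these markers. The difference was 0.477 without high depression tumour 3. A greater fibroblast content or activity in these tumours may remain as a hypothesis, and its link to depression was not tested beyond the group comparison.

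The third pattern is the excess of higher over lower probe sets at 1.5-fold. Of these 73.3% were higher, or 66% after quantile normalization, while 42.8% of all probe sets were higher. Without low depression tumours 1 and 4 the share higher was 53.2%, against 56.6% to 72.1% without any other pair of low depression tumours. Lower probe sets went from 371 to 854 and higher ones from 1018 to 972. Counts from 5 against 3 tumours are not comparable with those from 5 against 5, however. Without other pairs, higher ones numbered 994 to 1862 and lower ones 487 to 993, so this pair left the fewest higher ones. Its removal also takes out any biology of these 2 tumours, so it does not show that low RNA quality produced the higher ones. Low RNA quality stays open as an explanation. A biological difference between those tumours and the rest stays open as well, since both also had the lowest proliferation means of their group, 6.80 and 5.47.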
